A study of Danio rerio with 6 samples.

How the data were processed

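The data are read counts per gene from the eyes of single zebrafish larvae at 5 days post fertilization, from an intercross of samd7 heterozygotes. Per the labels' protocols, larvae were genotyped from the rear of the body, eyes of 1 larva made 1 replicate, 3 WT and 3 samd7-/- larvae were used, and 10 ng of total RNA went into a SMARTer Ultra Low library with 12 cycles of cDNA and 12 cycles of library amplification, read as 150 bp pairs. This kit does not mark the strand, so reads of overlapping and antisense genes are not separated, and reads of near-identical gene copies may be split among them. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to its sample by name.

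Per the submitters' processing notes, the tools were Trim Galore 0.6.1, STAR 2.7.2b, HTSeq 0.9.1, DESeq2 1.34.0 and R 4.1.3, with genome build danRer10. The annotation is not given in the sources used here. The deposited value per gene and library is a normalized signal: a read count divided by 1 size factor per library, as the values themselves show. The authors also deposited a log2 fold change and an adjusted p-value per gene, named as DESeq2 names them per the file headers. These 2 columns were used only as an alternative and are called the authors' deposited table.

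Every value of a library was a whole multiple, within 0.001, of the value of 1 read, for 100% of values in all 6 libraries. Whole reads could thus be recovered, in total 26672265, 23387568 and 26020445 for WT and 23550042, 23252010 and 23185755 for samd7-/-. For samd7-/- 2 the value of 1 read, 1.01, lies so near 1 that an automatic check of the recovery did not accept it, so tests on recovered reads rest on the multiples alone for that library. DESeq2 1.42.0 on the recovered reads gave the fold changes of the authors' deposited table within 0.001 for 99.98% of genes, with 3 outside. Reads carry no molecular identifiers, so intervals (95%) and floors (3 counts) cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom lay between 44.3 and 197. Of the tested genes, 13.1% had genotypes that did not overlap, where chance gives 10%.

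The main test was limma 3.58.1 in R 4.3.3, limma-trend on log2(value + 1) with 2 groups and no covariate, 2-sided, on genes with a value of at least 10 in at least 3 of the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 14781 genes, 935 were at 0 in all libraries and 11959 were tested. Fold changes on this scale understate those of genes near 0. Single ratios and shares were compared with exact permutation tests, for which 3 against 3 cannot give a p under 0.1. The tests, the gene lists and the alternatives were fixed before the data were examined, except edgeR 4.0.16 (quasi-likelihood test on the recovered reads, 11951 genes), the rod list with directly matched symbols only, the shares and sums of opsins and arrestins, the chromosome count with libraries left out or with DESeq2 and edgeR calls, and the share of genes on each chromosome at an unadjusted p under 0.05. The other alternatives were the replicate number as a block, each library left out, no filter, a minimum of 50, DESeq2, quantile normalization, TMM factors, pseudocounts of 0.5 and 10, robust moderation, array weights and the authors' deposited table.

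Genes were named by a fixed rule: samd7, every visual opsin, the 8 largest rises and 8 largest falls among genes that passed with a mean of at least 50, non-overlapping genotypes and a symbol that is not a clone name, and from each list up to 4 members that passed with the smallest p, or the 1 with the highest mean where none passed. Any other gene named in the text was chosen after its values were seen.

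The 32 lists were visual opsins, non-visual opsins, rod genes, shared cone phototransduction, UV and blue cone genes, red and green cone genes, photoreceptor transcription factors, photoreceptor outer segment and synapse genes, circadian clock genes, Polycomb components, Hox genes, other developmental factors, p53 and cell death genes, stress and immediate early genes, glial and inflammatory response genes, mitochondrial genes, cytosolic ribosomal proteins, and markers of the pineal organ, pigment epithelium, lens, cornea and skin, Muller glia, bipolar, horizontal, amacrine and ganglion cells, dividing cells, blood, vessels, muscle, microglia, and iridophores. Lists share members. For 36 list symbols the table's gene was found through a synonym in RefSeq's gene table (assembly GRCz12tu), a rule set after the gene names had been seen; of the rod list, 3 of 17 were found this way, and 9 of the 14 direct matches fell. Lists were tested with camera at a preset correlation of 0.01 over the 30 lists with members past the filter; no Hox gene passed it, and the mitochondrial list, set by the form of the gene name, was empty, since no gene name in the table had that form. With an estimated correlation 0 lists passed. fry was run as an alternative in 2 forms, which ask whether a list's genes move one way on balance (directional) or change in either direction (mixed), without comparing them with other genes.

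Chromosomes were taken from the same RefSeq table. As it describes another assembly than the one the reads were aligned to, it served only to tell which genes neighbour samd7, on its chromosome or within 10 Mb in that assembly: 14483 of 14781 genes, 11825 of 11959 tested genes and all 36 called genes had a place.

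The fits were tested on simulated data drawn for this comparison, with a dispersion of 0.02 for every gene. The 200 genes changed were drawn from those with a mean of at least 50. Some real genes varied more, as rho did in samd7-/- (67122 ± 27006), so the rates below need not hold for them. With 200 genes changed, against 36 called in the real data, the adjusted threshold was also easier to pass. In the real data opn1lw1, fitted 5.62-fold higher in samd7-/-, did not pass (limma, adjusted p = 0.0863). A gene that did not pass is not shown to be unchanged. limma recovered 98.5% of 67 genes changed 2-fold and 100% of those changed 4-fold and 8-fold, with 15 false calls over 11996 genes. edgeR recovered 98.5, 100 and 100% with 13 false calls over 12015 genes, and DESeq2 92.5, 100 and 100% with 14 over 14781. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.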

Results

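RNA was measured in the eyes of 6 zebrafish larvae at 5 days post fertilization, 3 wild type (WT) and 3 homozygous for a mutation in samd7 (samd7-/-), all born to heterozygous parents. Each library came from the eyes of 1 larva, so the spread between libraries holds differences between animals together with those of dissection and library preparation. samd7 encodes a SAM domain protein of the Polycomb group of chromatin regulators that is made in photoreceptors, and the study asks how it keeps photoreceptor types and their opsins apart. The WT libraries held 26672265, 23387568 and 26020445 reads assigned to genes, and the samd7-/- libraries 23550042, 23252010 and 23185755. Values below are normalized read counts, given as mean ± SD over n = 3 larvae per genotype, and log2 fold changes are samd7-/- over WT on the log2(value + 1) scale with their standard error (SE), tested with limma. Of 14781 genes, 11959 were tested.

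The samd7 transcript itself was higher in the mutants. Its counts were 1813, 1587 and 1931 in WT and 4691, 4070 and 4479 in samd7-/-, a log2 fold change of 1.31 (SE 0.12, adjusted p = 0.0049). The labels do not describe the lesion, so a gain in transcript neither supports nor contradicts the genotype labels.

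Few genes passed the threshold between the genotypes, and with all 6 libraries most of those fell. At an adjusted p under 0.05, 5 genes rose (samd7, arr3b, exorh, pcyt1aa and tbx2a) and 31 fell, of which 4 and 30 changed at least 2-fold. Of these 36 genes, 24 belong to the gene lists fixed for the eye, mostly rod and cone genes, 7 of the others lie on the chromosome of samd7, and 5 lie elsewhere. DESeq2 on the recovered reads called 24 genes higher and 66 lower, all 36 among them, while edgeR called 4 and 30. The number of calls depended on single libraries: 9 without WT 1, 6 without WT 2, 6 without WT 3, 20 without samd7-/- 1, 27 without samd7-/- 2 and 20 without samd7-/- 3. Without WT 1 the calls were 5 higher and 4 lower, and with any other library left out more genes fell than rose. The genes aanat2, arr3a, opn1mw2, ppm1la and samd7 were called with any 1 library left out. No called gene changed sign in any setting, but the genotypes did not overlap for any of the 36, so leaving out 1 library could not turn a sign. The gene opn1mw1 was called with any samd7-/- library left out and could not be tested with 2 WT libraries, since the filter needs 3.

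Green cone opsin transcripts were nearly gone from the mutant eyes. opn1mw1, the most abundant green cone opsin here, stood at 315528 ± 90027 in WT and 0.989 ± 0.978 in samd7-/-, where 3 reads were seen over the 3 libraries (0, 1 and 2) against 952682 in WT. That is a WT over samd7-/- ratio of 316767, with a 95% counting interval of 108392 to 1536040 (adjusted p = 3.4e-07); its fitted log2 fold change of −17.37 depends on the pseudocount. opn1mw2 fell from 3258 ± 760 to 42.1 ± 16.9 (log2 −6.30, SE 0.32, adjusted p = 0.000104). The other copies were near the limit of detection in both genotypes, opn1mw3 with 18 reads in WT and 3 in samd7-/- (ratio 5.99, interval 1.75 to 31.7) and opn1mw4 with 6 and 8. The green opsin copies are similar in sequence, so how reads were split among them is uncertain, but their sum also differed, by a factor of 6826.

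The cone arrestins moved in opposite directions. arr3a, the arrestin of red and green cones, fell from 117637 ± 25840 to 988 ± 115 (log2 −6.88, SE 0.17, adjusted p = 5.9e-07). arr3b, the arrestin of ultraviolet (UV) and blue cones, rose from 141857 ± 15655 to 383875 ± 8951 (log2 1.44, SE 0.17, adjusted p = 0.0147). The share of arr3a in cone arrestin counts was 45.1 ± 5.15% in WT and 0.256 ± 0.0255% in samd7-/-, and the sum of both arrestins was 1.48 times as high in samd7-/- (exact permutation p = 0.1 for each, two-sided, the smallest that 3 against 3 can give). The arr3b call was lost with 5 of the 6 libraries left out in turn, at adjusted p = 0.0599 without WT 1, 0.0674 without WT 2, 0.099 without WT 3, 0.111 without samd7-/- 1 and 0.0757 without samd7-/- 3, with log2 fold changes from 1.37 to 1.53.

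Among 7 tested genes of the red and green cone list, 3 fell (opn1mw1, opn1mw2 and arr3a), 0 rose and 4 did not pass. With p-values adjusted over the list alone, 3 fell and 1, opn1lw1, rose. The main red opsin, opn1lw2, stood at 282512 ± 70493 in WT and 222662 ± 3474 in samd7-/- (log2 −0.32, 95% interval −0.79 to 0.16, adjusted p = 0.826). The minor red opsin opn1lw1 stood at 222 ± 46.6 and 1432 ± 972 (log2 2.49, SE 0.42, adjusted p = 0.0863). It passed with DESeq2 (adjusted p = 0.00119) and with samd7-/- 3 left out (adjusted p = 0.0318). thrb, the thyroid hormone receptor needed for red cones, had a log2 fold change of 0.15 (adjusted p = 0.857). As a group the list was lower (camera, adjusted p = 1.9e-06, and 0.22 with an estimated correlation). Its median log2 fold change was −0.32 and its mean −4.02, with 4 members negative and 3 positive. The group result thus rests on the 3 genes that fell. The list did not pass without WT 1 (adjusted p = 0.133) and passed without WT 2 (0.00683) and without WT 3 (0.004), 3 fits in which opn1mw1 is not tested.

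Among 8 tested genes of the UV and blue cone list, all had positive fold changes, 2 rose (arr3b and tbx2a), 0 fell and 6 did not pass. As many as 6 rose when adjusted over the list alone. tbx2a, a T-box factor that specifies UV cones, rose from 3863 ± 353 to 6855 ± 566 (log2 0.83, SE 0.12, adjusted p = 0.0332). The UV opsin opn1sw1 stood at 1005550 ± 242579 in WT and 1579590 ± 97175 in samd7-/- (log2 0.68, SE 0.27, adjusted p = 0.747). The blue opsin opn1sw2 stood at 217833 ± 44876 and 407017 ± 34657 (log2 0.92, SE 0.21, adjusted p = 0.303), and foxq2, a factor of blue cones chosen after its values were seen, at 634 ± 109 and 1204 ± 46.7 (log2 0.94, adjusted p = 0.055). DESeq2 called both (adjusted p = 0.000134 and 4.1e-05). As a group the list was higher (camera, adjusted p = 1.8e-10; adjusted p = 0.184 with an estimated correlation; median log2 fold change 0.75). The tbx2a call was lost with each of WT 1, WT 2, WT 3, samd7-/- 1, samd7-/- 2 and samd7-/- 3 left out (adjusted p = 0.0741 to 0.183) and with edgeR (adjusted p = 0.055). The number of genes that rose, 2, was 1 without WT 1 (neither arr3b nor tbx2a), 1 without samd7-/- 2 (arr3b) and 0 without any other library.

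The makeup of the cone opsin pool shifted. UV opsin took 55.1 ± 0.144% of cone opsin counts in WT and 71.4 ± 1.66% in samd7-/-, and blue opsin 12.0 ± 0.434% and 18.4 ± 1.3%. Red opsin took 15.5 ± 1.46% in WT and 10.2 ± 0.608% in samd7-/-, and green opsin 17.3 ± 1.39% and 0.0021 ± 0.000832%. For each of these 4 shares the 3 samd7-/- larvae lay on one side of the 3 WT larvae (exact permutation p = 0.1, the smallest possible). Losing green opsin alone raises the other shares of a fixed total. Among cone opsins other than green, a total chosen after the values were seen, UV opsin took 66.7 ± 1.24% in WT and 71.4 ± 1.66% in samd7-/-, blue opsin 14.5 ± 0.514% and 18.4 ± 1.3%, and red opsin 18.8 ± 1.48% and 10.2 ± 0.608% (exact permutation p = 0.1 for each, the smallest possible). The cone opsin total was 1.21 times as high in samd7-/- (exact permutation p = 0.3). Over the visual opsin list, 4 of 8 tested genes fell (opn1mw1, opn1mw2, rho and rhol), 0 rose and 4 did not pass. Adjusted over the list alone, 4 fell and 3 rose. The number that fell was 1 without WT 1, WT 2 or WT 3, where opn1mw1 is not tested, 3 without samd7-/- 1 and 2 without samd7-/- 3, where opn1lw1 rose. The list was lower as a group (camera, adjusted p = 0.000353; adjusted p = 0.325 with an estimated correlation), but not with a WT library left out (adjusted p = 0.437 without WT 1, 0.0778 without WT 2 and 0.101 without WT 3). In the same libraries the lens list took 15.0, 23.4 and 20.2% of reads in WT and 13.5, 17.2 and 12.4% in samd7-/-, ranges that overlap. That list was lower as a group at the preset correlation (camera, adjusted p = 7.6e-25; adjusted p = 0.325 with an estimated correlation), and none of its genes passed with limma (32 at an unadjusted p under 0.05, 0 with edgeR and 3 with DESeq2).

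**Figure D1:**
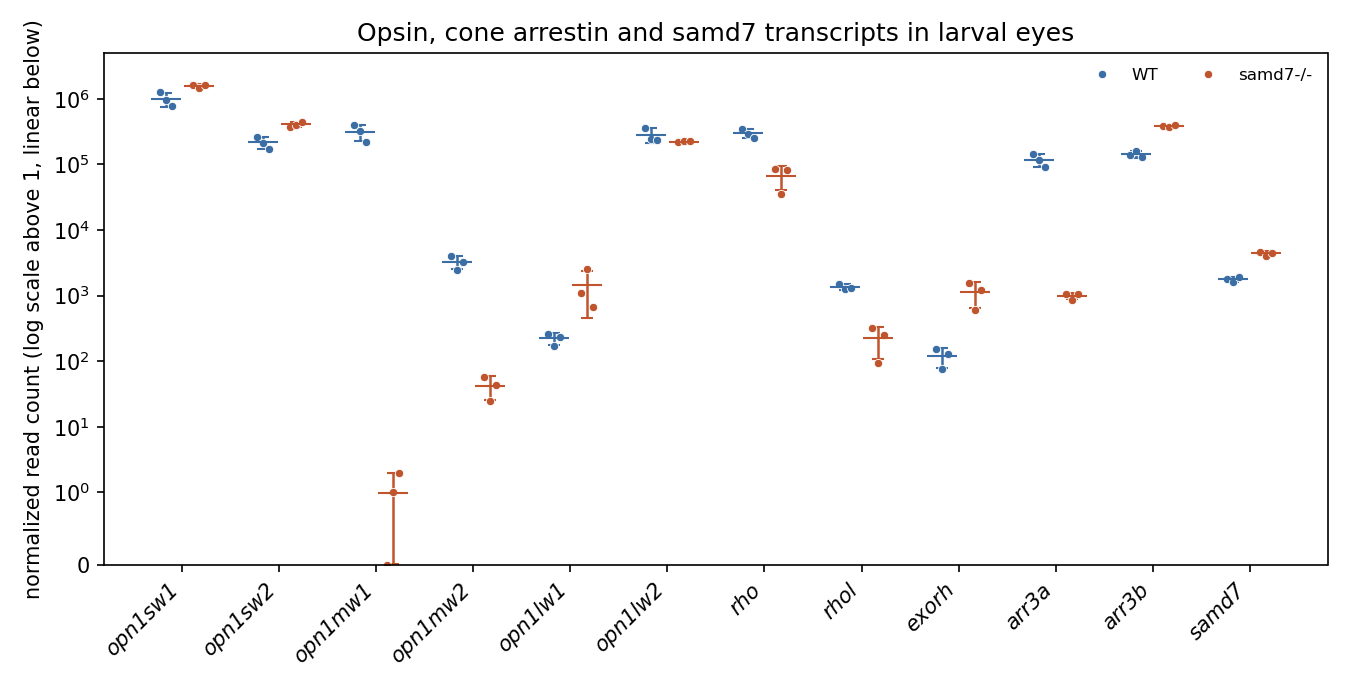
Normalized read counts (vertical axis, log scale above 1 and linear below) of visual opsins, exorh, the cone arrestins and samd7 in each WT (blue) and samd7-/- (orange) larva; points are the 3 larvae of a genotype, long horizontal lines their mean and bars 1 SD. opn1mw1 lies at 315528 on average in WT and at 0.989 in samd7-/-, and arr3b at 141857 and 383875.

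Most rod genes fell. Of 17 tested genes of the rod list, 12 fell, 0 rose and 5 did not pass, with log2 fold changes of the 12 from −1.52 to −2.90. There were 15 that fell when adjusted over the list alone. Rhodopsin, rho, fell from 298809 ± 46965 to 67122 ± 27006 (log2 −2.24, SE 0.32, adjusted p = 0.0362). The rod arrestins sagb and saga fell, sagb from 12673 ± 1953 to 1969 ± 765 (log2 −2.77, SE 0.29, adjusted p = 0.0102) and saga from 6721 ± 929 to 990 ± 503 (log2 −2.90, SE 0.36, adjusted p = 0.0202). The outer segment rim genes rom1a and rom1b fell by 2.55 and 2.74 on the log2 scale (adjusted p = 0.0096 and 0.0102). nr2e3, a transcription factor of rods, fell from 4896 ± 89.5 to 1729 ± 336 (log2 −1.52, SE 0.15, adjusted p = 0.0079). The rod transducin subunits gnat1 and gngt1 and the rod kinase grk1a, chosen after their values were seen, fell too (log2 −2.33, −2.14 and −2.21).

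The 5 rod genes that did not pass were pde6a (log2 −1.95, adjusted p = 0.055), guca1b (−2.40, adjusted p = 0.0766), gnb1b (−0.38), rcvrna (0.12) and nrl, the factor upstream of nr2e3 in rod development (−0.48). The rod list was lower as a group (camera, adjusted p = 2.7e-34; adjusted p = 0.184 with an estimated correlation; median log2 fold change −2.24). rhol, a rhodopsin-like gene outside this list, fell from 1353 ± 145 to 222 ± 116 (log2 −2.77, SE 0.40, adjusted p = 0.0354), a call lost without WT 1, WT 2, WT 3 or samd7-/- 3 (adjusted p = 0.0757 to 0.202). Single rod calls were fragile: 0 of the 12 passed without WT 1, 0 without WT 2, 0 without WT 3, 8 without samd7-/- 1 and 6 without samd7-/- 3, and 7 with robust variance moderation, while the median log2 fold change stayed between −1.88 and −2.52 with any 1 library left out. rho itself missed the threshold without a filter (adjusted p = 0.0508), with quantile normalization (0.1) and with robust moderation (0.0534). saga also lies on the chromosome of samd7, and the lens list had a median log2 fold change of −0.55 in the same libraries.

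exorh, the rhodopsin of the pineal organ, rose in the mutant eyes while rho fell. It stood at 119 ± 39.9 in WT and 1125 ± 474 in samd7-/- (log2 3.19, SE 0.37, adjusted p = 0.0155). Its counts were 0.0399 ± 0.0124% of the rho counts in WT and 1.68 ± 0.168% in samd7-/- (exact permutation p = 0.1, the smallest possible). It was the single gene of 17 tested non-visual opsins to pass, and also adjusted over the list alone. That list did not pass as a group in one direction (camera, adjusted p = 0.225, direction up, with a median log2 fold change of −0.00 and a mean of 0.28). The exorh call was kept only with samd7-/- 2 left out: adjusted p was 0.0736 without WT 1, 0.0534 without WT 2, 0.099 without WT 3, 0.0549 without samd7-/- 1 and 0.069 without samd7-/- 3, with log2 fold changes from 2.89 to 3.58.

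aanat2, which encodes an enzyme of melatonin synthesis made in the pineal organ and in photoreceptors, fell from 1958 ± 387 to 488 ± 36.9 (log2 −1.98, SE 0.16, adjusted p = 0.0033). exorh and aanat2 were the genes of the pineal list that passed, out of 14 tested. Adjusted over the list alone, 2 rose and 2 fell. asmt, which encodes the last enzyme of melatonin synthesis, had a log2 fold change of −0.13 (adjusted p = 0.87). The pineal list did not pass as a group in one direction (camera, adjusted p = 0.309, direction down, with a median of −0.13 and a mean of 0.02).

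Most genes of the phototransduction cascade shared by cone types did not pass. Of 19 tested, 0 rose, 2 fell and 17 did not pass. When adjusted over the list alone, 1 rose and 6 fell. The 2 were guca1a, which encodes a guanylate cyclase activator (1258 ± 137 to 463 ± 71.7, log2 −1.45, SE 0.16, adjusted p = 0.0102), and rgs9b, which encodes a regulator that switches transducin off (503 ± 62.3 to 170 ± 44.4, log2 −1.59, SE 0.22, adjusted p = 0.0332). Whole eyes were measured, so the values do not tell whether these 2 falls lie in cones. The cone transducin gnat2 stood at 102203 ± 8958 and 121659 ± 14936 (log2 0.25, adjusted p = 0.82), and the phosphodiesterase subunit pde6h, chosen after its values were seen, at 134646 ± 28703 and 65584 ± 9587 (log2 −1.02, adjusted p = 0.163; DESeq2 adjusted p = 3.2e-05). The list did not pass as a group in one direction (camera, adjusted p = 0.208, direction down, with a median of 0.13 and a mean of −0.32), except without samd7-/- 3 (down, adjusted p = 0.0468), and its direction turned with quantile normalization (adjusted p = 0.973). With WT 1, WT 2 or WT 3 left out 0 of the 2 calls were left, and without samd7-/- 1 or samd7-/- 2 only 1.

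Of 23 photoreceptor transcription factors tested, 1 rose (tbx2a), 1 fell (nr2e3) and 21 did not pass. Adjusted over the list alone, 4 rose and 1 fell. The broad photoreceptor factor crx stood at 17034 ± 1678 and 15478 ± 584 (log2 −0.13, adjusted p = 0.855). The nr2e3 call was lost with a WT library left out (adjusted p = 0.0599 without WT 1, 0.0534 without WT 2 and 0.0645 without WT 3), and the tbx2a call with any of the 6 (adjusted p = 0.0741 to 0.183). Of 21 outer segment and synapse genes, 3 fell, 0 rose and 18 did not pass, the same adjusted over the list alone: rom1a, rom1b and pdca, which encodes phosducin (1305 ± 132 to 287 ± 100, log2 −2.25, SE 0.27, adjusted p = 0.0155). Of these 3 calls, 0 were left without WT 1, WT 2 or WT 3 (adjusted p = 0.0534 to 0.111), and pdca lies on the chromosome of samd7. prph2b, a rim protein of rods and cones, had a log2 fold change of 0.13 (adjusted p = 0.915). Neither list passed as a group in one direction (camera, adjusted p = 0.118, direction up, and 0.309, direction down, the second with a median of 0.01 and a mean of −0.25), but the first passed with quantile normalization (adjusted p = 0.038).

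Few chromatin and developmental genes passed, and no Hox gene could be tested. Of 36 tested Polycomb components, 1 rose, samd7 itself, and 35 did not pass, the same adjusted over the list alone (camera, adjusted p = 0.0502, direction up). As a group the list passed with no filter (adjusted p = 0.0457), without WT 2 (0.0027) and without samd7-/- 1 (0.00887), and had an adjusted p of 0.555 without WT 1. Its only member at an unadjusted p under 0.05 was samd7, the mutated gene, and the list was not tested without it. The catalytic subunit ezh2 stood at 462 ± 109 and 586 ± 142 (log2 0.34, adjusted p = 0.834). Of 143 tested homeobox, T-box, forkhead and Sox factors outside the Hox clusters, 1 rose (tbx2a, lost with any 1 of the 6 libraries left out, adjusted p = 0.0741 to 0.183) and 142 did not pass. Adjusted over the list alone, 2 rose (camera, adjusted p = 0.111, direction up). None of the 48 Hox genes reached the filter, and 35 had any read, 177 reads over the WT libraries (47, 50 and 80) and 268 over the samd7-/- libraries (216, 29 and 23). Of 39 circadian clock genes, 0 passed with limma, 0 adjusted over the list alone, 0 with edgeR and 0 with DESeq2, against 1 at an unadjusted p under 0.05 (camera, adjusted p = 0.067, direction up). As a group the clock list was higher without WT 2 (adjusted p = 0.0177), without WT 3 (0.004), without samd7-/- 2 (0.00757) and with quantile normalization (0.038), and its direction turned without WT 1 (0.745).

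Markers of the other eye tissues held no gene that passed over all genes tested with limma. All 56 tested lens markers had negative fold changes, with a median log2 of −0.55. They were lower as a group at the preset correlation (camera, adjusted p = 7.6e-25), but did not pass with the estimated correlation of 0.58 (adjusted p = 0.325). Of these, 22 fell when adjusted over the list alone, 32 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 3. The most abundant, the crystallin crybb1, stood at 761125 ± 268323 and 524397 ± 114844 (log2 −0.50, adjusted p = 0.82). Of 77 cytosolic ribosomal protein genes, 76 had negative fold changes, with a median log2 of −0.28. They were slightly lower as a group at the preset correlation (camera, adjusted p = 6.1e-26), but did not pass with the estimated correlation of 0.85 (adjusted p = 0.379). The list took 7.16, 5.71 and 5.89% of reads in WT and 5.81, 5.52 and 5.55% in samd7-/-, ranges that overlap. In that list, 0 genes passed with limma, 0 adjusted over the list alone, 0 with edgeR and 0 with DESeq2, against 22 at an unadjusted p under 0.05. rplp0 stood at 90117 ± 16963 and 77264 ± 2602 (log2 −0.21). Both lists stayed lower at the preset correlation with any 1 library left out. Directional fry passed neither (adjusted p = 0.188 for lens and 0.217 for ribosomal genes).

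Ganglion cell, amacrine cell and vessel markers were slightly higher as groups at the preset correlation. Their estimated correlations were 0.26, −0.0008 and 0.06. Directional fry passed the amacrine list (adjusted p = 0.0453) but not the ganglion cell list (0.357) or the vessel list (0.157). Ganglion cell markers had a median log2 fold change of 0.25 over 23 genes (camera, adjusted p = 0.000498; adjusted p = 0.401 with an estimated correlation), amacrine markers 0.14 over 24 (adjusted p = 0.0032; adjusted p = 0.216 with an estimated correlation) and vessel markers 0.27 over 19 (adjusted p = 0.00113; adjusted p = 0.324 with an estimated correlation). In each of these, 0 genes passed with limma, 0 adjusted over the list alone, 0 with edgeR and 0 with DESeq2, against 2, 4 and 3 at an unadjusted p under 0.05. The most abundant, sncgb, calb2a and aqp1a.1, had log2 fold changes of 0.06, −0.06 and −0.12. Dividing cell markers had a median of 0.11 over 36 genes (camera, adjusted p = 0.00452; adjusted p = 0.668 with an estimated correlation; hmgn2 log2 0.04), lost without WT 3 (adjusted p = 0.796), without samd7-/- 2 (0.227) and without samd7-/- 3 (0.0554). Muscle markers had a median of −0.33 over 40 genes (camera, adjusted p = 0.0138; adjusted p = 0.68 with an estimated correlation; mylpfa log2 −0.47). Their direction turned without WT 1 (adjusted p = 0.385) and without samd7-/- 2 (0.729). In the dividing cell and muscle lists, 0 genes had an unadjusted p under 0.05, 0 passed with limma, edgeR or DESeq2 and 0 adjusted over the list alone. The estimated correlations of these lists were 0.52 and 0.70, and directional fry passed neither (adjusted p = 0.656 and 0.741).

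The remaining lists did not pass as groups with all 6 libraries and held 0 genes passing with limma, with edgeR, with DESeq2 or adjusted over the list alone. For Muller glia the camera adjusted p was 0.94 (direction up, median −0.00, mean 0.02; glula log2 0.06), for bipolar cells 0.118 (up; gnao1b 0.12), for horizontal cells 0.309 (up; tfap2b 0.31) and for retinal pigment epithelium and melanophores 0.0743 (down; rlbp1b −0.29). For cornea and skin it was 0.067 (down; krt4 −0.07), for blood 0.765 (up, median 0.08, mean −0.03; hbbe1.1 0.16), for microglia and macrophages 0.983 (up, median 0.01, mean −0.02; apoeb −0.18) and for iridophores and xanthophores 0.969 (up, median −0.08, mean 0.08; pnp4a −0.28). For p53 and cell death genes it was 0.208 (down; ccng1 −0.03), for stress and immediate early genes 0.19 (down; gstp1 −0.09) and for glial and inflammatory response genes 0.668 (up; stat1a 0.09). In these lists, the genes at an unadjusted p under 0.05 numbered 2 for Muller glia, 1 for horizontal cells, 2 for cornea and skin, 1 for blood, 1 for p53, 2 for stress and 2 for glial response, and 0 for the others. Some passed as groups in another setting: pigment epithelium was lower without WT 2 (adjusted p = 0.000581) and without samd7-/- 2 (9.4e-07), but turned up without samd7-/- 3 (0.568), and cornea and skin was lower without WT 2 (3.3e-05) and without samd7-/- 3 (0.0478). Bipolar markers were higher without WT 1 (adjusted p = 0.0309) and with quantile normalization (0.0282), and p53 genes were lower without WT 2 (0.022). At an unadjusted p under 0.05, 757 of all tested genes differed by limma, 803 by DESeq2 and 766 by edgeR. By limma, a split of the 6 libraries that mixed the genotypes gave up to 730, so this count alone does not show a difference by genotype.

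**Figure D2:**
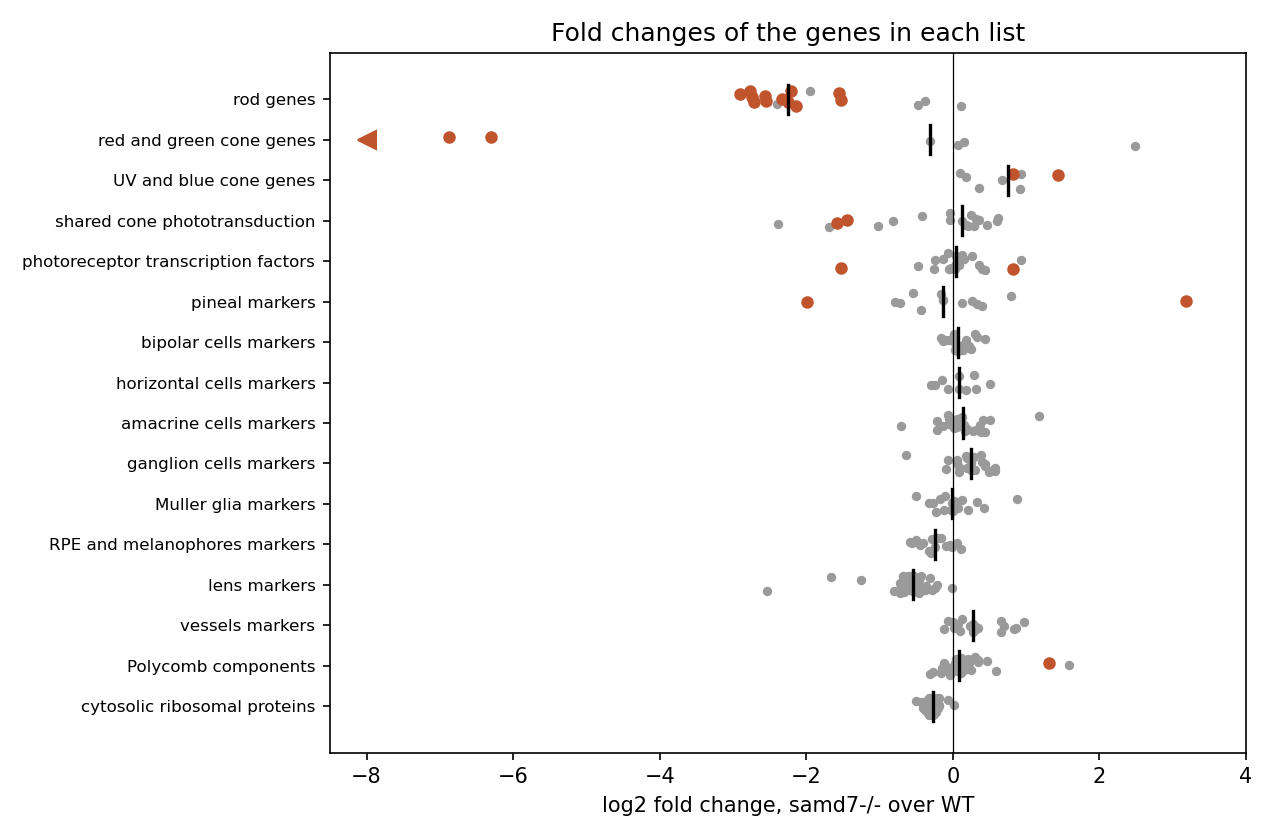
Log2 fold changes (horizontal axis, samd7-/- over WT) of the tested genes of 16 lists; each point is a gene, orange for an adjusted p under 0.05 over all tested genes, and black bars are list medians. The arrow stands for opn1mw1 at −17.37, outside the axis; the rod list has its median at −2.24 and the UV and blue cone list at 0.75.

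Genes on the chromosome of samd7 were called more often than others. With samd7 itself left out, 9 of 583 tested genes on that chromosome were called against 26 of 11241 elsewhere (odds ratio 6.76, Fisher's exact test p = 3.6e-05). The 9 were ppm1la, saga, pdca, pcyt1aa, pik3r2, cplx4c, tfa, klhl18 and si:dkeyp-73d8.9. Another chromosome held 5 of the 26 calls, among 418 tested genes. Fisher's exact test counts genes as independent, although all were measured in the same larvae. ppm1la, which encodes a protein phosphatase, fell from 1257 ± 119 to 464 ± 5.93 (log2 −1.43, SE 0.12, adjusted p = 0.0041), and pcyt1aa, which encodes an enzyme of phosphatidylcholine synthesis, rose from 108 ± 27.1 to 418 ± 31.5 (log2 1.97, SE 0.22, adjusted p = 0.0134). si:dkeyp-73d8.9 had 70 reads in WT and 0 in samd7-/-, at least 23.3-fold lower against a floor of 3 counts over the group. Apart from pcyt1aa, pdca and saga, the 9 genes were named after their values were seen. The pcyt1aa call was lost without WT 3 (adjusted p = 0.0712), samd7-/- 1 (0.0734) and samd7-/- 3 (0.069). The number called on the chromosome of samd7, 9, was 3 without WT 1, 2 without WT 2, 1 without WT 3, 3 without samd7-/- 1, 4 without samd7-/- 2 and 2 without samd7-/- 3.

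At an unadjusted p under 0.05 the share was 15.4% on that chromosome, the highest of 25, against 5.87% elsewhere and 10.0% on the next. Within 10 Mb of samd7, 2 of 200 genes were called (odds ratio 3.55, Fisher's exact test p = 0.118), but with DESeq2 10 of 200 (odds ratio 7.79, p = 2.2e-06), and 12 of 383 further away on the chromosome (odds ratio 5.47, p = 8.4e-06). The odds ratio without 1 library was 11.6 without WT 1 (p = 0.0055), 12.9 without WT 2 (p = 0.0218), 4.83 without WT 3 (p = 0.223), 3.64 without samd7-/- 1 (p = 0.0639), 3.54 without samd7-/- 2 (p = 0.0364) and 2.28 without samd7-/- 3 (p = 0.239), all by Fisher's exact test on 5 to 26 calls. The share at an unadjusted p under 0.05 stayed higher on that chromosome with any 1 library left out, from 10.2 to 17.6% against 3.75 to 8.1% elsewhere.

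**Figure D3:**
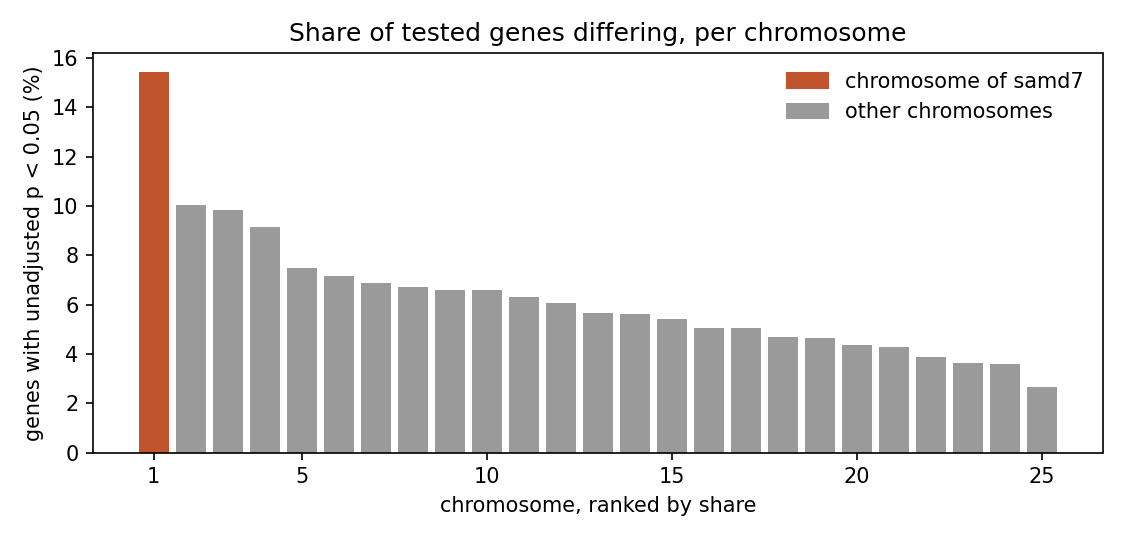
Share of tested genes at an unadjusted p under 0.05 (vertical axis, percent) on each of 25 chromosomes ranked by that share (horizontal axis), with the chromosome of samd7 in orange and samd7 itself left out. It stands at 15.4%, above the next at 10.0%.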

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

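The edgeR test, the rod list without synonyms, the cone opsin shares and, on chromosomes, the counts with a library left out or with DESeq2 and edgeR and the shares at an unadjusted p were chosen only after the results were seen. Passing the threshold depended on the setting. None of the 36 called genes changed sign in any setting, but their genotypes did not overlap, so leaving out 1 library could not turn a sign. DESeq2 on the recovered reads and the authors' deposited table each gave 24 genes higher and 66 lower, 9 and 47 of them at least 2-fold, and array weights gave 8 higher. Leaving out 1 library at a time gave 1 to 5 higher and 4 to 23 lower, and 1 to 4 and 4 to 23 at least 2-fold. With a WT library left out, 3 of the 36 genes could not meet the filter and 5 or 6 of the others were still called, against 18 to 26 with a samd7-/- library left out; each such fit has fewer libraries. Of the gene lists, 11 passed with the preset correlation, 0 with an estimated correlation and 5 with directional fry (visual opsins, rod, UV and blue cone, red and green cone and amacrine lists). Mixed fry, which asks for change in either direction, passed 12: these 5, shared cone phototransduction (adjusted p = 1.4e-05), photoreceptor transcription factors (6.0e-06), outer segment and synapse (0.000668), pineal (3.3e-05), non-visual opsins (0.0294), Polycomb (0.00138) and vessels (0.0316). The Polycomb list holds samd7, its only member at an unadjusted p under 0.05, so its pass does not show a change of the other members. The odds ratio of calls on the chromosome of samd7 was 3.55 within 10 Mb (2 calls) and ranged from 2.28 to 12.9 with 1 library left out. Where the number of libraries or calls does not explain a change, the cause was not tested.

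Among single named genes outside the libraries left out, calls ended for rho in 3 settings, saga with robust moderation (adjusted p = 0.0566), rhol with robust moderation (0.0787) and array weights (0.0536), gnat1 and gngt1 with robust moderation (0.0832 and 0.0622), cplx4c with no filter (0.0529), si:dkeyp-73d8.9 with a pseudocount of 10 (0.0619), and tbx2a and arl13a with edgeR (0.055 and 0.0677). opn1lw1 and opn1sw2 passed with DESeq2, and opn1sw2 also with quantile normalization (0.0474). Whether replicate numbers pair the samples could not be settled with only 3 numbers. The same-numbered libraries' deviations correlated at 0.03, 0.18 and −0.00, and 3 of 6 libraries matched their own number best. With the replicate block 4 genes were higher and 29 lower, 29 of the 33 shared with the 36; the 7 that did not pass with it were rgs9b (adjusted p = 0.0502), zgc:158258 (0.055), cplx4c (0.0842), tfa (0.086), tbx2a (0.104), si:dkeyp-73d8.9 (0.119) and arl13a (0.143). With it the Polycomb list, which includes samd7 itself (adjusted p = 0.0324), and the cornea and skin list (0.00187) passed. Depth limits the genes near 0 reads: ndufs8b and si:dkeyp-73d8.9 have only a floor, opn1mw1 in samd7-/- a wide counting interval, and opn1mw3, opn1mw4 and the Hox genes few reads in both genotypes.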

Other observations

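All tests of explanations in this part, and the gene choices below, were made only after the results were seen. Outside the lists and the chromosome of samd7, 5 genes were called, each lower in all 3 samd7-/- libraries. ndufs8b, a subunit gene of mitochondrial complex I, had 728 reads in WT (normalized counts of 394, 181 and 140) and 0 in samd7-/-, at least 242-fold lower against a floor of 3 counts over the group (adjusted p = 0.000810). zgc:77752 fell from 445 ± 55 to 62.5 ± 19.5 (log2 −2.86, adjusted p = 0.0056), zgc:162144 from 579 ± 14.3 to 95.1 ± 31.9 (log2 −2.65, adjusted p = 0.0054), zgc:158258 from 590 ± 152 to 173 ± 25.8 (log2 −1.74, adjusted p = 0.0238) and arl13a from 3980 ± 226 to 2443 ± 124 (log2 −0.70, adjusted p = 0.0389). The zgc:158258 and arl13a calls were lost with any 1 library left out, arl13a also with edgeR (adjusted p = 0.0677), and the zgc:77752 and zgc:162144 calls with any WT library left out. The mutant libraries also differed among themselves: samd7-/- 1 held 216 of the 268 Hox reads, and samd7-/- 2 held the fewest rho reads (0.153% of its reads, against 0.363 and 0.359%).

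DESeq2 alone called genes that limma did not. Among its higher calls were bace1 (706 ± 101 to 1252 ± 43.8, DESeq2 adjusted p = 0.00013), the vacuolar ATPase subunit gene atp6v0b, which lies within 10 Mb of samd7 (4203 ± 589 to 7042 ± 153, 0.000152), and the neuronal connexin gene cx35b (2685 ± 226 to 3886 ± 318, 0.0311). Among its lower calls were the lens crystallin gene crygm2a (349 ± 181 to 60.2 ± 35.9, 4.5e-06), the retinol binding protein gene rbp2a (1364 ± 373 to 466 ± 179, 7.4e-05) and the metallothionein gene mt2 (2747 ± 630 to 1534 ± 185, 0.00473). Their limma adjusted p-values were 0.0658, 0.0673, 0.268, 0.139, 0.178 and 0.238.

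Of the 10 ways to split the 6 libraries into 3 and 3, only the real one (1 of 10) gave as many called genes, 36 against at most 3 in the others. At an unadjusted p under 0.05 the real split gave 757 genes by limma and the others 314 to 730. With 10 splits the share cannot go under 0.1, so they are too few to judge chance.

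The loss of green opsin reads and the gain of the minor red opsin both concern gene copies of similar sequence. Reads moved among the green copies would leave their sum near its WT level, but the sum was 6826 times lower in samd7-/-, which argues against that as the cause. Reads of opn1lw2 placed on opn1lw1 at a fixed rate would keep the opn1lw1 share of red opsin near its WT value, but that share was 7.99 times as high (0.0796% against 0.636%), and 5.01 times without samd7-/- 2, with all 3 samd7-/- libraries above all 3 WT libraries. Why these opsins differ between the genotypes was not tested further.

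Most rod genes fell while exorh rose. Scaling is an unlikely cause of the fall, since the median rod log2 fold change was −2.23 with quantile normalization. Whether the fall is 1 common factor, as fewer rods alone would give, cannot be told apart from a change in rod gene activity. Against rho, 6 of 11 called members fell further and 2 less. Against the list mean, in a second form of the test chosen after the first was seen, 0 of 17 fell further and 3 (gnb1b, nrl and rcvrna) less. This second form used a spread shared over all tested genes, with an SE for sagb of 0.37 against 0.089 in the first. It could thus miss departures of the size seen against rho. Pineal tissue in the dissected eyes as the source of exorh could not be judged from aanat2, an abundant pineal transcript that fell (log2 −1.98). Retinal photoreceptors make aanat2 too, and in WT it stood at 1958 against 119 for exorh. A fall in the retina could thus hide a small pineal addition. Over the 3 samd7-/- libraries exorh followed the rod mean more closely than all but 1.95% of 3276 genes of like level (64 genes), which is consistent with rods as its source, but 3 libraries are too few to decide.

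Calls gathered on the chromosome of samd7, where samd7-/- larvae carry the mutated haplotype near the gene. Alleles linked to the mutation may account for part of them: with the photoreceptor and pineal lists left out, 7 of 577 genes there were called against 5 of 11147 elsewhere, an odds ratio of 27.3 (Fisher's exact test p = 4.3e-07), and 11.1 on the DESeq2 calls. Reads of that haplotype failing to align to the reference would favour lower counts in samd7-/-. Of 20 DESeq2 calls there outside those lists, 13 were lower (65%) and 7 higher (exact binomial p = 0.263), so this cannot be told apart from real differences in expression. Among the affected genes, saga and pdca are in the photoreceptor lists, and their falls may mix both. The lists need not hold every photoreceptor gene, so calls counted outside them may include some, and the odds ratio of 27.3 depends on the lists.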
